A study of Oncorhynchus mykiss with 24 samples.

How the data were processed

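Gene expression was measured in total RNA from pooled hearts of rainbow trout on a custom trout array of Agilent with 1 colour (Cy3). The 24 arrays held 8 groups of 3 biological replicates, with water containing 32 µg/l retene or DMSO alone for 1, 3, 7 or 14 days. Samples were assigned to groups by their titles, which were checked against the treatment, time and replicate in their other labels. The number of hearts per pool (15 or 45) was copied from the labels. Of the 18 pools before day 14, 4 had 15 hearts, and all pools of day 14 had 45.

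The deposited scanner files held intensity values per spot on a linear scale, written by Agilent Feature Extraction 10.7.1 with the protocol GE1_107_Sep09 per the file headers. The processed signal is the background-subtracted and spatially detrended brightness, with no normalization between arrays. The submitters' processing notes also name limma, without a version or a role. The deposited series table holds the authors' processed intensity values, which matched a quantile normalization of the processed signal on a linear scale, with replicate spots averaged, to within 0.085%. Every one of its 24 columns had a median of 153.0. It has no centring, and its direction is that of brightness. The table was used as an alternative only.

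Each array carried 62976 spots and 61360 probes. Control spots were left out, as were spots marked as uneven or as outliers among replicate spots, and replicate spots of a probe were averaged. There were no saturated spots. Values were log2 of the processed signal minus the 75th percentile of each array. Probes were tested when they were well above background on all 3 arrays of at least 1 group and had at least 2 unmarked values in every group, which left 47306 probes. On these, a model with a mean for each of the 8 groups was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 2.15). The comparisons were retene against DMSO at each day, their average over the days, an F test of the difference between days with its pairwise differences, and DMSO hearts between days. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes. Differences are given on the log2 scale with the standard error of the fit, and SDs are those of the arrays of a group.

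Probe names were contigs for 45197 probes, RefSeq transcripts for 28 and other sequence names for 16135. The RefSeq names were looked up, without versions, in a RefSeq gene table of assembly USDA_OmykA_1.1, which was used for symbols only. It named 26 probes of 24 genes, 19 with a descriptive symbol and 5 with a LOC symbol, and left 2 unmatched. No coordinates are given. The genes cyp2k4, mmp and nr1i2 were too dim to be tested. The genes anp and nppb had 2 probes each. The brighter one represents the gene, and both probes of each gene gave the same calls. Genes were named by a rule set before the data were examined. It takes, for each comparison, up to 10 rises and 10 falls among called genes whose groups did not overlap, all measured members of the AhR battery, up to 4 members of each list that passed its set test, and for the difference between days the 10 named genes with the smallest adjusted p. Members of the lists that were not called, actb, the DMSO value of mmp9 between 7 and 14 d and LOC100135875 at 7 and 14 d were named in addition, after their values were seen.

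Gene lists for pathways and cell types were fixed before the data were examined, 29 in all. A list needed 4 measured members. Only the AhR battery had them (cyp1a3, cyp1c1, cyp1c2 and cyp1c3) and was tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Another 7 lists had 1 to 3 members on the array. These were gstr for phase II conjugation, gpx1 for oxidative stress defence, kcnh2 for ion handling, LOC100135863 for glycolysis, mmp9 for extracellular matrix, anp, nppb and vnp for cardiac development and load, and kcnh2 again for endothelium, a match made only by its synonym ERG, which is also the name of an unrelated endothelial gene. The other 21 lists had none, among them heat shock and unfolded protein response, sarcomere, cell cycle, ribosomal proteins, oxidative phosphorylation, fatty acid oxidation, sterol synthesis, hypoxia, p53, immediate early genes, clock, interferon, thyroid and steroid signalling, and iron and haem. The markers of blood, liver and yolk, skeletal muscle, immune cells, epicardium, epidermis and nerve were also among these 21, so the cell composition of the pools could not be examined.

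The arrays lay on 3 slides of 8, each slide with 1 array of every group. Slide was tested as a fixed block and differences were also taken within each slide. The other alternatives were normexp background correction (offset 50, on the median signal, since the files have no mean signal column), quantile normalization, scaling on 9 spike-in probes, no filter on dim probes, only probes above background on all arrays (39381), marked spots kept, replicate number as a block, pool size as a covariate, only pools of 45 hearts, eBayes with trend and robust, arrayWeights, only the arrays of the 2 groups compared, a minimum change of 2-fold, the series table, and leaving out each array in turn. Quantile normalization and the slide block, each without DMSO replicate 1 of day 1, were added after that array had been seen to stand apart. Correlations of log2 differences between days and with control development were taken across tested probes and compared with all 20 assignments of the 6 arrays of a day (exact two-sided permutation). Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

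The fit was tested on simulated data with the spread that the fit gave each probe. Values were drawn independently between probes and with 1 spread of a probe for all arrays. They hold no array as uneven as DMSO replicate 1 of day 1. The shares recovered and false below therefore need not hold for these arrays, above all where DMSO at 1 d is compared. For retene against DMSO at 1 d, over 47306 probes, 10.4% of simulated changes of 0.5 (log2), 68.7% of changes of 1 and 90.9% of changes of 2 were recovered. For the average over the days these shares were 62.7%, 94% and 98.5%, and for the difference between days 4.5%, 29.9% and 80.3%. For the difference between days the change was put into retene hearts at 14 d only. Of the probes called in these simulations, 5% were false at 1 d, 2.3% at 3 d, 7.6% at 7 d, 5% at 14 d, 10.1% for the average, 6.2% for the difference between days and 3.4% for DMSO hearts.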

Results

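RNA was measured in hearts dissected from newly hatched rainbow trout kept in water with 32 µg/l retene, a polycyclic aromatic hydrocarbon that activates the aryl hydrocarbon receptor (AhR), or in water with the carrier DMSO alone. Hearts were taken after 1, 3, 7 and 14 days, which gave 8 groups of 3 biological replicates and 24 arrays. Most samples were pools of 45 hearts. The other 4 were pools of 15 hearts, namely replicate 3 of DMSO at 1 d, retene at 1 d and DMSO at 7 d, and replicate 2 of DMSO at 3 d. The labels state that the smaller pools were used where the RNA of the larger ones was of insufficient quality. Each 1-colour array read 61360 probes, of which between 67.9% and 78.8% were well above background, and 47306 entered the tests. The lowest of these shares belonged to replicate 1 of DMSO at 1 d, an array that stood apart in several measures, so the main counts are also given without it. Arrays have no read depth, and their number limits the precision. Names could be given to 24 genes, of which 21 were tested. The remaining probes carried contig or sequence names that no table paired with a gene.

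The first question, from the title of the series, was what retene changed in the heart. Among the named genes, the largest changes were rises of cytochrome P450 genes that the activated AhR switches on. The gene cyp1a3, which encodes a cytochrome P450 1A monooxygenase that oxidises polycyclic aromatic hydrocarbons, was 123-fold higher with retene at 1 d (log2 difference 6.94 ± 0.29, SE, n = 3 per group, adjusted p = 2.84e-11). It was still 47.9-fold higher at 14 d (5.58 ± 0.29, adjusted p = 1.1e-09). Its relatives cyp1c1, cyp1c2 and cyp1c3 rose by 155-, 176- and 139-fold at 1 d and by 79.7-, 72.7- and 88.2-fold at 14 d. At 3 and 7 d the rises were 48.8- and 67.7-fold for cyp1a3, 88.1- and 85.8-fold for cyp1c1, 127- and 103-fold for cyp1c2, and 120- and 64.8-fold for cyp1c3. In DMSO hearts the cyp1c genes were close to the background. Of the 3 DMSO arrays at 1, 3, 7 and 14 d, cyp1c1 was well above background on 2, 3, 2 and 1, cyp1c2 on 1, 2, 3 and 3, and cyp1c3 on 1, 3, 3 and 3, so their folds rest on DMSO signals near the limit of the measurement. With normexp background correction the rises at 1, 3, 7 and 14 d were 48.8-, 29.1-, 17.7- and 14-fold for cyp1c1, 27.4-, 30.2-, 28.6- and 19.3-fold for cyp1c2, and 30.8-, 32.9-, 25.3- and 22.8-fold for cyp1c3. The sizes of the cyp1c folds are therefore uncertain, while cyp1a3 stayed at 113-, 48.1-, 64.8- and 46.4-fold. The largest adjusted p of these 4 genes over the 4 days was 2.48e-09. All retene arrays lay above all DMSO arrays for each of these genes on each day. Each gene was thereby higher in all 12 comparisons within a slide and day. On single slides the differences for cyp1a3 ran from 6.67 to 7.21 at 1 d and from 4.61 to 6.17 at 3 d on the log2 scale.

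**Figure D1:**
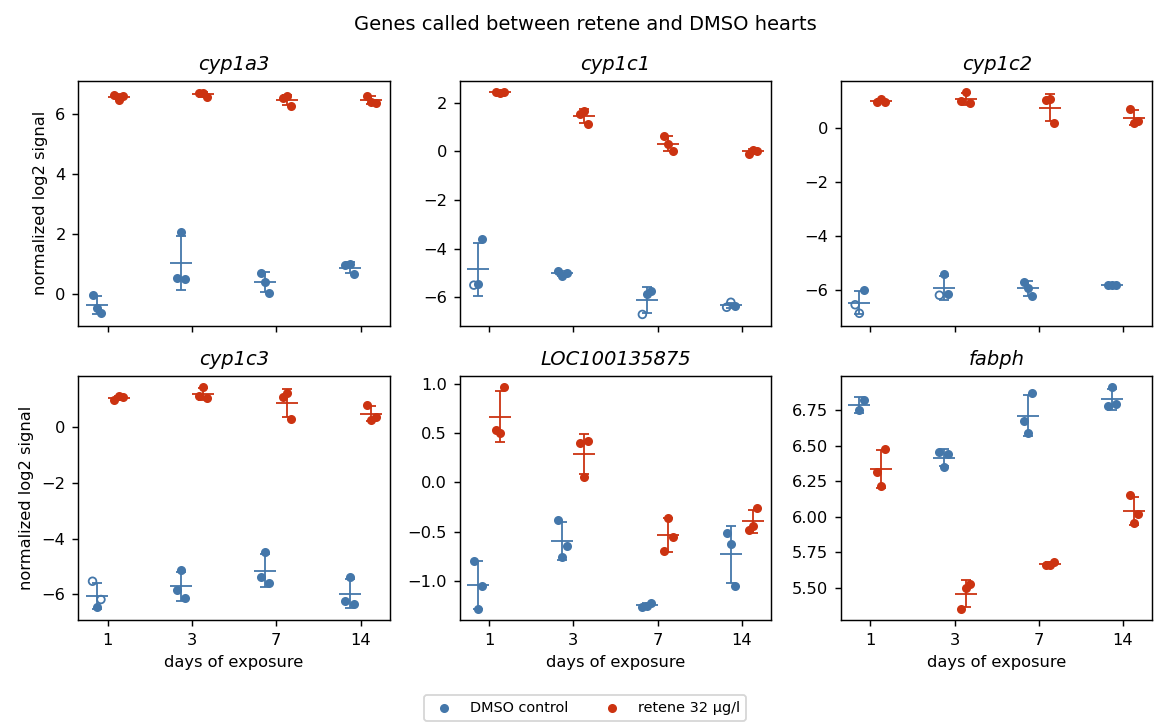
Normalized log2 signal (y axis) of 6 genes by days of exposure (x axis) in DMSO (blue) and retene (red) hearts. Points are single arrays (open where the spot was not well above background), horizontal marks are group means and bars are the SD over 3 arrays (2 for fabph in DMSO at 1 d). Retene arrays lie above every DMSO array of the same day for the 4 cyp1 genes, and below for fabph.

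These 4 genes were all the measured members of the AhR battery, a list of AhR target genes fixed before the data were examined. The median log2 difference of the list was 7.2 at 1 d, 6.68 at 3 d, 6.25 at 7 d and 6.25 at 14 d. All 4 members were higher on every day, adjusted over all probes and also adjusted over the list alone. The competitive set test camera was run with the same model over 44678 genes and unnamed sequences with values on all arrays, 1 probe each. It gave a p of 1.73e-34 at 1 d, 1.07e-35 at 3 d, 1.92e-35 at 7 d and 1.15e-37 at 14 d. With an estimated correlation between members the p values were 1.37e-07, 1.07e-07, 1.13e-07 and 7.32e-08. With slide as a block the camera p was at most 2.52e-33, and the medians on single slides ran from 7.08 to 7.74 at 1 d, 6.32 to 6.94 at 3 d, 6.07 to 6.58 at 7 d and 5.82 to 6.42 at 14 d.

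The named gene that fell on every day was fabph, which encodes the heart-type fatty acid binding protein, a carrier of fatty acids inside muscle cells. Its log2 difference was -0.45 ± 0.10 at 1 d (adjusted p = 0.0289), -0.95 ± 0.09 at 3 d (adjusted p = 4.29e-06), -1.04 ± 0.09 at 7 d (adjusted p = 2.07e-06) and -0.78 ± 0.09 at 14 d (adjusted p = 8.94e-05), with n = 3 per group except 2 DMSO arrays at 1 d. Every retene array was lower than every DMSO array of its day, and the differences on single slides ran from -0.53 to -0.35 at 1 d, -0.996 to -0.912 at 3 d, -1.18 to -0.93 at 7 d and -0.95 to -0.62 at 14 d. The missing DMSO value at 1 d is a spot that the scanner software marked as uneven on replicate 1. With that spot kept, the difference at 1 d turned to 0.86 (adjusted p = 0.559), and the calls of the other days ended because the spread grew while their differences stayed at -0.95, -1.04 and -0.78. The series table, in which that spot is kept, ended the calls at 3, 7 and 14 d as well (-0.95, -0.954 and -0.772, adjusted p = 0.66, 0.618 and 0.755). The call at 1 d was also lost with slide as a block (-0.437, adjusted p = 0.0534), with only the pools of 45 hearts (-0.483, adjusted p = 0.105) and with no filter on dim probes (adjusted p = 0.0526). It was lost as well without DMSO replicate 2 or 3 or retene replicate 1 or 2 of that day (-0.489, -0.412, -0.44 and -0.39, adjusted p = 0.0534, 0.0816, 0.0926 and 0.138). The fall was not called on any day when arrays were scaled on the spike-in probes, where the differences were -0.708, -0.587, -0.754 and -0.605 (adjusted p from 0.285 to 1).

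A further gene, LOC100135875, which the reference table gives no descriptive name, was higher by 1.71 ± 0.17 at 1 d (3.28-fold, adjusted p = 3.06e-06, n = 3 per group) and by 0.88 ± 0.17 at 3 d (adjusted p = 0.00717). Its differences of 0.71 at 7 d (adjusted p = 0.0526) and 0.34 at 14 d (adjusted p = 0.502) did not pass. The slide differences were 1.33, 1.79 and 2.03 at 1 d and 1.15, 0.44 and 1.06 at 3 d. The 7 d difference was called in 14 of the 40 alternatives, among them without DMSO replicate 1 of day 1 (adjusted p = 0.0282), with spike-in scaling (1.001, adjusted p = 0.0451) and with arrayWeights (adjusted p = 0.00705). Without the pools of 15 hearts the 3 d difference was not (0.80, adjusted p = 0.0574).

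Over all tested probes, the response at 1 d took in 717 probes, 255 higher and 462 lower. Among them, 143 rose and 55 fell by at least 2-fold. The balance between rises and falls changed with the settings. Without the array of DMSO replicate 1, 606 probes were called, 360 higher and 246 lower, and 436 probes were called in both fits. With slide as a block 695 probes were called. The groups of 716 of the 717 did not overlap, which fixes 1 direction on every slide. That direction was counted on all 3 slides for 696, and a probe without a value on a slide was not counted. It is therefore no separate check. After scaling on spike-in probes, 75 were higher and 20 lower, with only the arrays of the 2 groups 71 and 2, and with arrayWeights 1037 and 1064.

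At 3 d, 787 probes were called, 435 higher and 352 lower, of which 158 rose and 24 fell by at least 2-fold. At 7 d, 350 were called, 205 higher and 145 lower, with 126 rises and 58 falls of at least 2-fold. At 14 d, 398 were called, 260 higher and 138 lower, with 128 rises and 29 falls of that size. The groups of all of these probes did not overlap, so their 1 direction on all 3 slides is no separate check. With slide as a block 743, 365 and 367 were called. DMSO replicate 1 of day 1 enters these comparisons only through the shared estimate of the spread, and without it the counts rose to 1764, 656 and 953 and contained all the probes called before. With spike-in scaling 183 were higher and 4 lower at 3 d, 198 and 2 at 7 d, and 85 and 0 at 14 d. That scaling moved the median difference of all probes to -0.28, 0.37, 0.25 and 0.12 on the log2 scale at the 4 days, against -0.10, -0.0011, -0.04 and -0.06 for the percentile scaling. At 1 d the median moved further down while most calls were lost, so the shift does not account for the fewer falls called there.

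**Figure D2:**
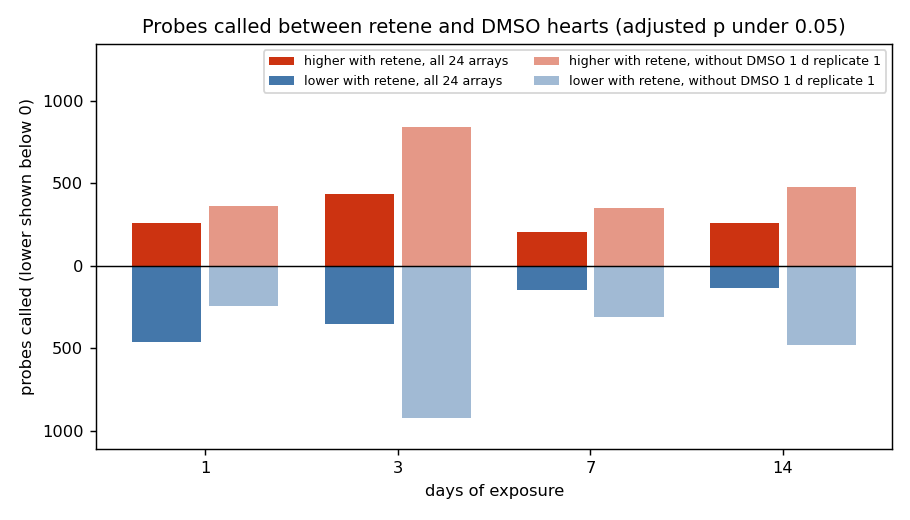
Number of probes called between retene and DMSO hearts (y axis, lower probes drawn below 0) by days of exposure (x axis), with all 24 arrays (full colour) and without replicate 1 of DMSO at 1 d (pale). At 1 d the called probes were 255 higher and 462 lower with that array, and 360 higher and 246 lower without it.

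The next comparison asked which changes held on average over the 4 days. Besides the 4 cyp1 genes, fabph (-0.81 ± 0.05, adjusted p = 1.64e-09) and LOC100135875 (0.91 ± 0.08, adjusted p = 5.94e-07), the averaged fit called 3 named genes with smaller changes. The gene mmp9, which encodes a protease that degrades extracellular matrix, fell by 0.52 ± 0.11 on the log2 scale (adjusted p = 0.00528) and was lower in 11 of the 12 comparisons within a slide and day. The gene kcnh2, which encodes a potassium channel of the cardiac action potential, fell by 0.37 ± 0.09 (adjusted p = 0.0204) and was lower in all 12. The gene gstr, which encodes a glutathione S-transferase, an enzyme that conjugates oxidised compounds, was higher by 0.22 ± 0.06 (adjusted p = 0.0437). That call was lost in 24 of the 40 alternatives, slide as a block among them (0.221, adjusted p = 0.0566), while the difference stayed between 0.185 and 0.386. The calls of mmp9 and kcnh2 were lost with spike-in scaling (-0.356 and -0.203, adjusted p = 0.48 and 0.688), and that of kcnh2 without the pools of 15 hearts (-0.354, adjusted p = 0.0531). With the uneven spot of day 1 kept, fabph had -0.48 (adjusted p = 0.416), and with the series table -0.449 (adjusted p = 0.455).

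The natriuretic peptide genes, which heart muscle expresses under stretch, were all bright and showed no call on any day. Averaged over the days, the log2 differences were -0.07 ± 0.07 for anp, -0.07 ± 0.09 for nppb and -0.02 ± 0.07 for vnp. The cytoskeletal actin gene actb was not called either (-0.06 ± 0.07), while gpx1, which encodes a glutathione peroxidase, had -0.42 ± 0.15 with an adjusted p of 0.1. It was called without DMSO replicate 1 of day 14 (-0.519, adjusted p = 0.0179) and with arrayWeights (adjusted p = 0.037). In all, 6 of the 21 named genes were higher and 3 lower in the averaged fit. The 3 natriuretic peptide genes were the measured members of the list for cardiac load, which held too few for a set test.

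**Figure D3:**
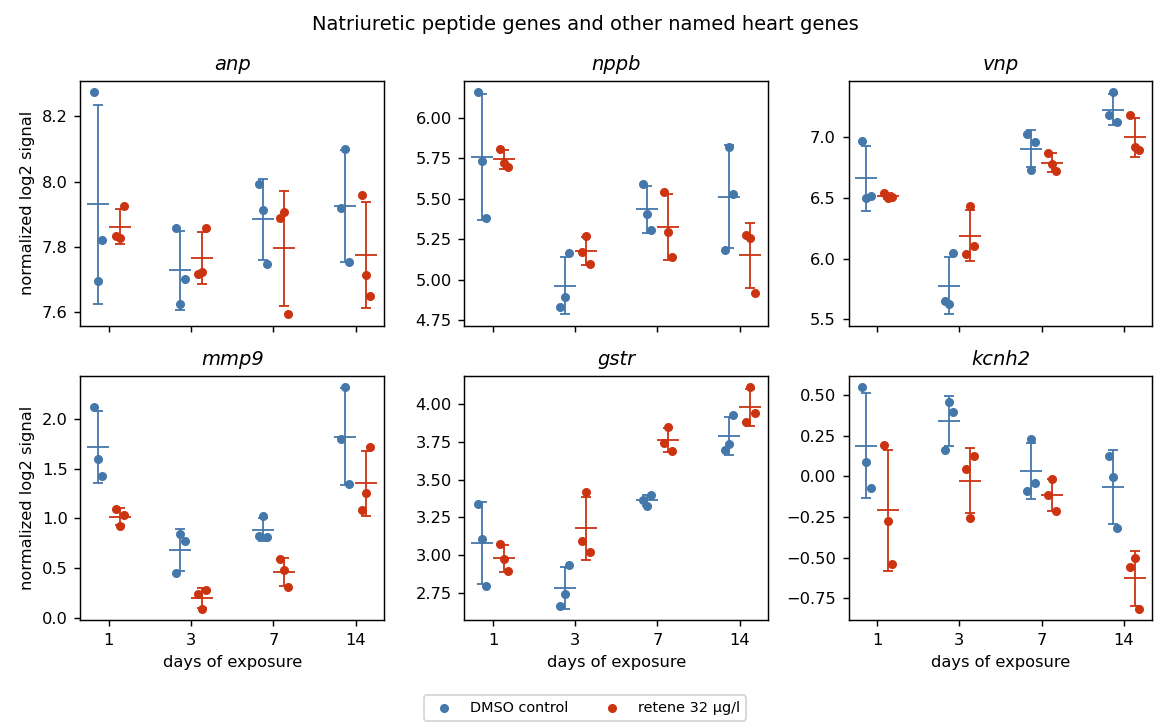
Normalized log2 signal (y axis) of 6 heart genes by days of exposure (x axis) in DMSO (blue) and retene (red) hearts. Points are single arrays, horizontal marks are group means and bars are the SD over 3 arrays. The DMSO and retene arrays of anp, nppb and vnp overlap on all 4 days, while mmp9 and kcnh2 have lower retene means on all 4 days.

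Over all tested probes, the averaged fit called 3236, of which 1093 were higher and 2143 lower. Most of these changes were small, and only 200 rises and 32 falls reached 2-fold. Without DMSO replicate 1 of day 1 the counts were 1780 higher and 2442 lower, and with slide as a block 3139 probes were called. Spike-in scaling gave 648 higher and 60 lower. Contigs without a gene name were ranked only where they were called in the same direction on all 4 days. Among these, TC172935 and TC172774 had the largest averaged rises, 6.91 ± 0.18 and 6.78 ± 0.13 on the log2 scale. The largest averaged falls among them were those of TC192858 and TC184359, -1.91 ± 0.11 and -1.55 ± 0.06.

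A core of probes responded throughout. On all 4 days 91 probes were higher and 18 lower, cyp1a3, the 3 cyp1c genes and fabph among them. The median log2 difference of the 91 was 1.94, 1.94, 1.70 and 1.45 at 1, 3, 7 and 14 d, and that of the 18 was -0.80, -0.89, -1.04 and -0.78. Probes called on 2 days overlapped far more than independent calls would. The days share 1 estimate of the spread of each probe, so their calls are not independent even without a shared effect. The numbers for independent calls are therefore only a rough reference. No probe was called in opposite directions at 7 and 14 d. At 7 and 14 d, 138 probes were higher on both days against 1.13 for independent calls, and 48 were lower against 0.423. Most probes were nevertheless called on a single day, 379 of the 647 that were higher on any day and 779 of the 906 that were lower. With DMSO replicate 1 of day 1 left out these were 760 of 1213 and 1249 of 1553. A call on a single day does not show that a probe differed between days. The F test of that difference called 38 probes, and only 10.4% of simulated changes of 0.5 (log2) were recovered at 1 d. The count common to all 4 days was 144 without DMSO replicate 1 of day 1 and 108 with slide as a block.

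Across all tested probes, the log2 differences of 7 and 14 d had a Pearson correlation of 0.623 (Spearman 0.396), where the other 5 pairs of days had between 0.141 and 0.22. With DMSO replicate 1 of day 1 left out, the pairs of 1 d with 3, 7 and 14 d had 0.263, 0.299 and 0.228. For 3 and 14 d the correlation was 0.073 without DMSO replicate 3 of day 3, 0.314 without DMSO replicate 2 of day 3 and 0.342 without retene replicate 3 of day 14. Probes are not independent replicates, so the arrays of 1 day were reassigned to retene and DMSO in all 20 ways. The exact two-sided permutation p for 7 and 14 d was 0.1, the smallest this design allows, and 0.2 after Benjamini-Hochberg adjustment over the 6 pairs. An assignment with mixed groups reached 0.526. On single slides the correlation was 0.208, 0.31 and 0.697.

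Whether the response differed between the days was tested directly. An F test over the 4 days called 38 probes, none of them a named gene, and the largest effect was at 1 d for 18 of them, at 3 d for 14, at 7 d for 1 and at 14 d for 5. Among the named genes the smallest adjusted p was that of LOC100135875 (0.0751), followed by fabph (0.267), cyp1a3 (0.497), cyp1c2 (0.53), vnp (0.568), LOC100136244 (0.614), gstr (0.649), cin (0.724), hig1a (0.766) and cyp1c3 (0.779). The lower folds of the cyp1 genes at the later days were therefore not shown to differ from those at 1 d. The F test called 209 probes without DMSO replicate 1 of day 1, LOC100135875 among them (adjusted p = 0.0289), 39 with slide as a block and 1 with spike-in scaling.

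The DMSO hearts show what changed without retene over the same days. From 1 to 14 d the natriuretic peptide gene vnp rose by 0.57 ± 0.14 on the log2 scale (adjusted p = 0.0068, n = 3 per group) and gstr by 0.71 ± 0.13 (adjusted p = 0.000568). Also higher were cyp1a3 (1.25 ± 0.29, adjusted p = 0.00381), LOC100136253 (1.06 ± 0.31, adjusted p = 0.0153) and pgmrc2 (0.38 ± 0.10, adjusted p = 0.0113). The glycolytic gene LOC100135863, for which the reference table gives the synonym gapdh, was lower by a log2 difference of -0.36 ± 0.12 (adjusted p = 0.0257), a call lost without DMSO replicate 1 of day 1 (-0.19, adjusted p = 0.119), with quantile normalization (-0.273, adjusted p = 0.054), with arrayWeights (-0.146, adjusted p = 0.095) and with the series table (-0.242, adjusted p = 0.0627). The gene cyp1c1 was lower too (-1.46 ± 0.35, adjusted p = 0.00503), though well above background on only 1 of the 3 arrays at 14 d, and its difference was -0.833 without DMSO replicate 3 of day 1, -0.833 with only the pools of 45 hearts and -0.586 with normexp. Spike-in scaling ended all of these calls but that of cyp1c1. The differences were then 0.404 for vnp, 0.544 for gstr, 1.089 for cyp1a3, 0.902 for LOC100136253, 0.215 for pgmrc2 and -0.521 for LOC100135863 (adjusted p from 0.0625 to 0.603). Leaving out 1 array ended the calls of LOC100136253 (0.90 without DMSO replicate 1 of day 14, adjusted p = 0.0689) and pgmrc2 (0.31 without replicate 3 of day 14 and 0.24 without replicate 2 of day 1, adjusted p = 0.0642 and 0.0578). The call of LOC100135863 was lost without any 1 of the arrays of day 14 as well (-0.352, -0.347 and -0.376, adjusted p at most 0.0647).

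The changes were not steady over time. By 3 d the natriuretic peptide genes nppb and vnp were first lower than at 1 d, by log2 differences of -0.80 ± 0.18 and -0.88 ± 0.14 (adjusted p = 0.00617 and 0.000771), and mmp9 was lower by -1.03 ± 0.21 (adjusted p = 0.00356). The genes cin (-0.77 ± 0.12), hig1a (-0.69 ± 0.14), LOC100136244 (-0.44 ± 0.14) and fabph (-0.37 ± 0.10) were lower as well, and cyp1a3 was higher by 1.41 ± 0.29 (adjusted p = 0.00355). At 7 d mmp9 (-0.83 ± 0.21), cyp1c1 (-1.25 ± 0.35), hig1a (-0.43 ± 0.14) and actb (-0.39 ± 0.14) were below their level at 1 d, and pgmrc2 (0.37 ± 0.10) was above it. The gene mmp9 was higher again at 14 d than at 7 d (0.94 ± 0.21, adjusted p = 0.0209). Without DMSO replicate 1 of day 1 the calls of LOC100136244 at 3 d and of hig1a and actb at 7 d were lost (-0.238, -0.287 and -0.18), and with that array's uneven spot kept fabph at 3 d turned to 0.945 (adjusted p = 0.306). Without DMSO replicate 2 of day 3, a pool of 15 hearts with the highest cyp1a3 of the DMSO arrays (2.09), the rise of cyp1a3 at 3 d was 0.89 (adjusted p = 0.0067). With only the pools of 45 hearts it was 0.77 (adjusted p = 0.0127). Without DMSO replicate 1 of day 7 the calls of cyp1c1, hig1a, actb and pgmrc2 at 7 d ended (-0.952, -0.338, -0.435 and 0.351, adjusted p = 0.0834, 0.126, 0.0619 and 0.0516). So did those of hig1a and actb without replicate 2, of actb without replicate 3, and of pgmrc2 without replicate 2 of day 1 (-0.437, -0.392, -0.335 and 0.229, adjusted p = 0.0613, 0.0871, 0.12 and 0.0693). Other settings ended calls at 7 d too, only pools of 45 hearts for pgmrc2 (0.378, adjusted p = 0.0565) and no filter on dim probes for actb (adjusted p = 0.0588). For mmp9 it was the slide block without DMSO replicate 1 of day 1 (-0.632, adjusted p = 0.0592). Without DMSO replicate 3 of day 1 cyp1c1 at 7 d was at -0.621, and it was at -0.806 with only the pools of 45 hearts and at -0.617 with normexp. The call of fabph at 3 d ended without replicate 2 of day 3 (-0.335, adjusted p = 0.0691). It also ended without replicate 3 of day 1 (-0.331) and with only the pools of 45 hearts (-0.297), where 1 DMSO value of day 1 was left. The call of LOC100136244 ended in 24 of 40 alternatives, with differences between -0.641 and -0.238. Spike-in scaling ended all of the calls against 1 d except that of cyp1c1, while most of the differences grew. At 3 d they were -0.988 for nppb, -1.075 for vnp, -1.225 for mmp9, -0.963 for cin, -0.877 for hig1a, -0.628 for LOC100136244, -0.643 for fabph and 1.221 for cyp1a3 (adjusted p from 0.06 to 0.2). At 7 d they were -0.93 for mmp9, -0.528 for hig1a, -0.485 for actb and 0.269 for pgmrc2 (adjusted p from 0.0846 to 0.541). The AhR battery had a median of 0.45 at 3 d (camera p = 0.0179), which did not pass with an estimated correlation (p = 0.105).

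Over all tested probes, 14031 were called between 14 and 1 d, 5038 higher and 8993 lower, and 3503 of them changed by at least 2-fold. With slide as a block 13703 were called. Of the 14031, 12894 had groups that did not overlap, and 12847 had values and 1 direction on all 3 slides. The excess of falls depended on the settings, since 7638 were higher and 6085 lower without DMSO replicate 1 of day 1. The submitters' quantile-normalized table gave 7186 higher and 7691 lower, arrayWeights 10414 and 9848, and spike-in scaling 607 and 3931. Against 1 d, 8614 probes were called at 3 d and 13864 at 7 d, and 1461 between 14 and 7 d. With DMSO replicate 1 of day 1 left out these counts were 6019, 12428 and 3936.

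**Figure D4:**
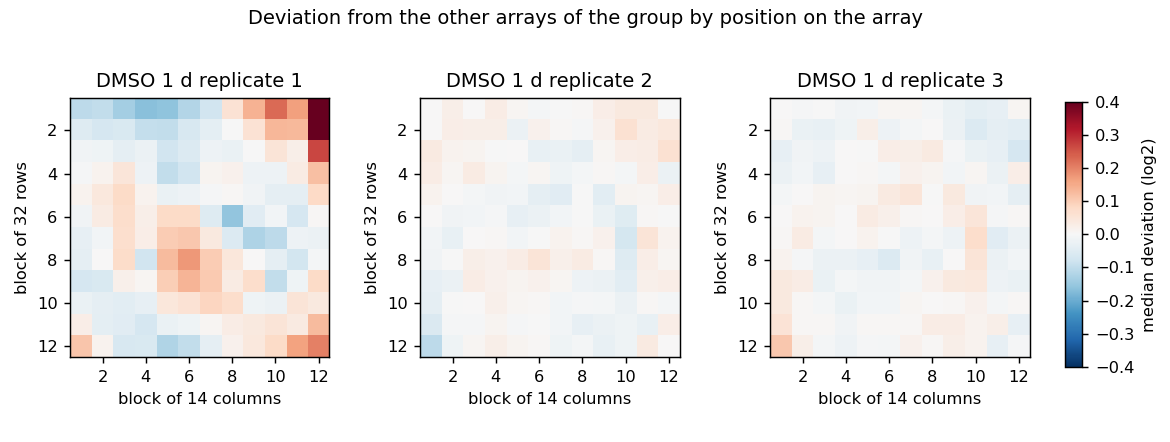
Median deviation (colour, log2) of the probes in each block of 32 rows and 14 columns of the array (y and x axes) from the other DMSO arrays of day 1, replicate 1 itself not used as a reference. The SD of these medians is 0.106 for replicate 1 and at most 0.0311 for any of the other 23 arrays.

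To ask whether retene hearts resembled an earlier or later control stage, the retene differences were correlated across all tested probes with the change between DMSO hearts of other days. The Pearson correlations were 0.05 at 1 d and 0.25 at 3 d with the change from 7 to 14 d, -0.13 at 7 d with that from 1 to 14 d, and -0.02 at 14 d with that from 1 to 7 d. The Spearman values were 0.09, 0.19, 0.17 and 0.06. Exact two-sided permutation p values over the 20 assignments of the arrays of each day were 0.4, 0.3, 0.7 and 0.9, and 0.8, 0.8, 0.9 and 0.9 after Benjamini-Hochberg adjustment over the 4 relations, so none differed from the spread between replicates. The smallest p this design allows is 0.1. On single slides the values ran from -0.01 to 0.11, 0.004 to 0.36, -0.24 to 0.08 and -0.33 to 0.03.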

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

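The tests of uneven hybridisation and of a different pool, both tests of the balance at 1 d, the regroupings for the difference between days, and the comparison of 7 and 14 d with control development were chosen after the results they explain had been seen.

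Retene effects differed between days for 38 probes by the F test over the 4 days, all without a gene name. The effect common to the days was taken off before the arrays were regrouped within the days. Only 1 of 100 such regroupings, the real one, called as many, and the highest other count was 2. This share is the smallest these draws allow. Mixed groups also take retene effects of single days into their spread, which lowers their counts. Chance is therefore made unlikely for this count but not excluded. By pairwise tests of the difference, limma called 5 probes between 3 and 1 d, 10 between 7 and 1 d, 89 between 14 and 1 d and 11 between 14 and 3 d. It called 0 between 14 and 7 d (1632 at an unadjusted p under 0.05) and 0 between 7 and 3 d (3041 unadjusted). Without DMSO replicate 1 of day 1 these counts were 28, 35, 162, 51, 0 and 129. The 5 probes between 3 and 1 d have no gene name. The retene effect on LOC100135875 was smaller at 14 d than at 1 d, with a difference of -1.38 on the log2 scale (adjusted p = 0.0195). Its adjusted p over the 40 alternatives ran from 0.00125 to 0.604, the highest with spike-in scaling, and the difference from -1.542 to -1.025. The call was lost without the pools of 15 hearts (adjusted p = 0.094) and without DMSO replicate 1 or 2 of day 14, retene replicate 1 or 2 of day 14 or retene replicate 3 of day 1 (adjusted p from 0.0508 to 0.0684).

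The array of DMSO replicate 1 at 1 d stood apart from the other 23. It held 2474 spots marked as uneven, against at most 34 on any other, and its mean correlation with the other 2 arrays of its group was 0.9439, where the next lowest of any array was 0.9665. Replicate spots of 1 probe differed by a median CV of 9.47% on this array and by 2.72% to 3.93% on the others, and deviations from the group followed the position on the array, which points to uneven hybridisation or drying. A different pool of hearts is argued against as the whole cause, since it would give no pattern by position, and the variance of the block medians was 11.7 times the highest of the other arrays. A wrong label is argued against as well, since the array correlated best with its own group (0.946), cyp1a3 was at the DMSO level (-0.01, where the lowest retene array had 6.28), and each of its mates correlated with it better (at least 0.9419) than any array of another day (at most 0.9369), though the mean of retene at 1 d was close at 0.943.

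At 1 d more probes were lower than higher with retene, 462 against 255. Without DMSO replicate 1 only 40.6% of the called probes were lower, so this array may account for the excess. The percentile scaling was not shown to be the cause, since 71.7% were lower with quantile normalization. The series table, also quantile-normalized, gave 63.1%. The 66.2% with normexp cannot bear on this, as that setting keeps the percentile scaling. With spike-in scaling 21.1% were lower, but only 95 probes were called, 75 higher and 20 lower. The median of all probes moved further down (-0.2799 against -0.1003). The falls were smaller, since 55 of the 462 reached 2-fold, against 143 of the 255 rises. Spike-in medians also varied within groups, from 10.929 to 11.621 (log2) for DMSO at 3 d. A setting with a wider spread would lose small changes first, so the balance of the few spike-in calls cannot decide on the scaling. Whether this is why more falls lost their call was not tested. The scaling stays open, and the settings were compared for this only after the result was seen. No biological explanation was tested for this balance.

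The differences at 7 and 14 d correlated at 0.623 across all tested probes and at 0.573 across the 45758 probes not called on any day. Differences between pools that also occur within groups stay open, since the replicate arrays at 1 and 3 d deviated along the shared direction by a median absolute correlation of 0.086, but by up to 0.37 for DMSO at 3 d. The main 2 directions of variation between arrays also showed such differences. DMSO replicate 3 of day 7, a pool of 15 hearts (84.81 and 22.27), lay near DMSO replicate 2 of day 14 (82.6 and 20.5). Retene replicate 3 of day 14 (47.62 and -35.15) lay near retene replicate 1 of day 7 (52.51 and -41.34). Both replicates 3 lay on the slide with a correlation of 0.697, against 0.208 and 0.31. Leaving out either moved the correlation by under its SD over slides (0.258). Leaving out both was not tested. Arrays on 1 slide stay open too, since differences taken on the same slide correlated better by 0.181 than those from different slides. A shift of retene hearts along control development had a correlation of 0.128 in size at most, with an SD over the slides of up to 0.2, too wide to decide. A response to retene shared by both days, which the design names, is also open, and these explanations cannot be told apart with 3 pools per group.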

How the results depend on the processing

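The settings that combine another choice with leaving out DMSO replicate 1 of day 1 were chosen after seeing the data. The shift of the AhR battery kept its direction and its call at all 4 days under every alternative run for it (camera p at most 9.1e-26 when arrays were left out, at most 1.37e-07 with an estimated correlation), and cyp1a3, cyp1c1, cyp1c2 and cyp1c3 kept theirs in every comparison of retene with DMSO. Of 2343 values of named genes under alternatives, 2177 kept their side of the threshold, 146 lost the call, 16 gained it and 4 reversed. The 4 were called values that changed sign, while uncalled values of either sign count as kept. The averaged difference of actb thus ran from -0.104 to 0.101 with no change counted. Leaving out an array outside the groups of a comparison cannot move its difference, only its spread. The reversed ones were fabph at 1 d (0.864 with marked spots kept, 0.88 with the series table) and fabph in DMSO hearts at 3 against 1 d (0.945 and 1.015), through 1 uneven spot on DMSO replicate 1 of day 1. The log2 difference of cyp1c2 at 1 d, whose DMSO signal was near the background, ran from 4.78 to 7.70 over the alternatives.

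Counts for 1, 3, 7 and 14 d, the average, the difference between days and DMSO hearts at 14 against 1 d were 717, 787, 350, 398, 3236, 38 and 14031. A minimum change of 2-fold, which by its construction calls fewer, gave 198, 182, 184, 157, 232 and, for the DMSO hearts, 3503. Spike-in scaling gave 95, 187, 200, 85, 708, 1 and 4538, and arrayWeights 2101, 2127, 1440, 1278, 6158 and, for the difference between days, 971. Only the pools of 45 hearts, with fewer arrays, gave 356, 426 and 184 at 1, 3 and 7 d, 2031 for the average and 24 for the difference between days. Only the arrays of the 2 groups, also fewer, gave 73, 126, 180 and 178 for the days and 3643 for DMSO hearts. For the difference between days, quantile normalization gave 63, probes above background on all arrays 62, marked spots kept 118, trend and robust 81, and 127 came from the series table. Without DMSO replicate 1 of day 1, quantile normalization gave 1801, 577 and 856 at 3, 7 and 14 d and 177 for the difference, and the slide block 1652, 637, 873 and 128. With only the pools of 45 hearts, the count at 14 d, where all arrays were kept, was 417. Except for the effect of the bound, the cause of these changes was not tested, that of fewer arrays included.

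Leaving out 1 array gave 418 to 1350 probes at 1 d, 410 to 1764 at 3 d, 188 to 656 at 7 d, 211 to 953 at 14 d, 2513 to 4222 for the average, 19 to 209 for the difference between days and 9572 to 15040 for DMSO hearts. The highest counts came without DMSO replicate 1 of day 1, except at 1 d (1350 without DMSO replicate 2, 1096 without DMSO replicate 3) and for DMSO hearts (15040 without DMSO replicate 3 of day 1). Counts fell by over 1.5 times at 1 d without retene replicate 1, 2 or 3 (460, 430, 418), at 3 d without DMSO replicate 1 or 2 (502, 460) or retene replicate 1, 2 or 3 (487, 410, 438), at 7 d without DMSO replicate 2 or 3 (215, 188) or retene replicate 1 or 2 (189, 215), and at 14 d without DMSO replicate 1 or 2 (216, 250) or retene replicate 1 or 2 (240, 211). The difference between days moved that far to 60 without DMSO replicate 2 of day 1, to 24, 19 and 24 without retene replicate 1, 2 or 3 of day 1, to 21 without DMSO replicate 1 of day 14, and to 25 and 21 without retene replicate 1 or 2 of day 14. The count called on all 4 days (109) ran from 89 to 144. Correlations with control development ran from 0.013 to 0.103 at 1 d, 0.096 to 0.291 at 3 d, -0.191 to -0.011 at 7 d and -0.14 to 0.101 at 14 d. The camera p of the AhR battery ran from 1.21e-36 to 4.18e-27 at 1 d, 2.97e-41 to 9.1e-26 at 3 d, 2.01e-39 to 6.48e-28 at 7 d and 5.95e-40 to 1.25e-28 at 14 d.

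With replicate number as a block, 669, 756, 356 and 377 probes were called at the 4 days, 3115 for the average, 37 for the difference and 13821 for DMSO hearts. The numbers do not pair the samples, since deviations of arrays with the same number and day correlated at a median of 0.055, above 0.1 in 4 of 12 pairs, and 11 of 24 samples correlated best with their own number. Of the 10 splits of the 6 arrays of a comparison, 1, the real one, called as many at each day and for DMSO hearts, with the highest other at 11, 3, 1, 0 and 158 probes. With 10 splits no share can be under 0.05. For the average, only the real 1 of 100 regroupings called as many (highest other 1). Mixed groups hold retene effects, so chance is not excluded.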
